A study of Mus musculus with 7 samples.

How the data were processed

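Polyadenylated RNA from mouse spleen was measured in 7 samples, 3 labelled wild type (WT, genotype given as C57BL/6N) and 4 labelled Fpr2KO, a knockout of the formyl peptide receptor gene Fpr2. Per the labels' protocols, RNA was extracted with the Qiagen RNeasy Plus Universal Mini kit and libraries were made with a NEBNext Ultra II RNA kit. The background of the Fpr2KO mice, the sex of the mice and the strand setting of the counting were not given in the sources used here. The values analysed were raw read counts per Ensembl gene, deposited by the authors as 1 table with a column per sample. Per the submitters' processing notes, reads were checked with FastQC 0.10.1 and counted with HTSeq 0.10.0 on mm10 (GRCm38). The aligner and the annotation release were not given in the sources used here. The table held 55414 genes, all rows named a gene, and no column belonged to an unmapped sample. The counts were whole numbers with a different total in each sample, so a count model was used.

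Gene symbols and positions came from GENCODE M21 (GRCm38), matched on the gene ID. Of the IDs, 52081 matched and 3333 did not, and the matched IDs carried 99.8% of the counts. Total counts ran from 14968605 to 18692809 per sample. A floor of 3 counts in 1 library corresponded to between 0.156 and 0.201 CPM. Floors and counting intervals (exact Poisson, 95%) cover counting error only, because reads without molecular identifiers are not independent molecules.

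Groups were compared with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F test with robust estimation, after TMM scaling and filterByExpr at its defaults, which kept 16089 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and log2 fold changes are Fpr2KO minus WT. CPM values are counts scaled to a common library size with TMM factors. The targeted gene and list scores were also compared by exact two-sided permutation over the 35 splits of 7 samples into 3 and 4, for which the smallest possible p is 0.0286. Called genes within 10 Mb of Fpr2 were set against the rest of the genome by a two-sided Fisher exact test. The labels number the replicates without saying that each came from a separate animal, so p-values measure the spread between these samples.

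A set of 29 gene lists was fixed before the data were examined. They covered formyl peptide receptors, Fpr2 ligands with lipid mediator enzymes, neutrophils, monocytes, macrophages of the red pulp and of the marginal zone, dendritic cells, B cells with their marginal zone and germinal centre subsets, and plasma cells. Others covered T cells, regulatory and activated T cells, NK and cytotoxic cells, erythroid cells, megakaryocytes with platelets, mast cells with basophils and eosinophils, stromal cells and endothelial cells. Pancreatic acinar cells and adipocytes were included as tissues that lie beside the spleen. The remaining lists held type I interferon response, inflammatory cytokine, MHC class II, phagocyte NADPH oxidase with complement, immediate early with heat shock, circadian with glucocorticoid, proliferation and mitochondrially encoded genes. Lists with at least 3 tested genes, 27 in all, were compared with all other genes by limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01), two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and the fry rotation test were alternatives. A list score is the mean of its genes' log2 CPM, each centred over the 7 samples.

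Genes were named by a rule written before the data were examined. It took Fpr2, the other formyl peptide receptors and Nnt. It took the 12 largest changes in each direction among called genes with a mean of at least 1 CPM and no overlap between the groups, leaving out immunoglobulin and T cell receptor segments, genes named only Gm plus a number, Rik or an accession, and pseudogenes. Where no gene qualified in a direction, the 5 with the smallest p were taken and said not to have passed. From each list up to 4 members with the smallest p were added. The choice of 4 for lists that passed and 2 for the others was not part of the rule as first written. Some genes that the rule takes from the lists are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

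Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with quality weights, no low count filter, a filter of 1 CPM in 3 samples, each sample left out, a replicate block, library sizes without haemoglobin, immunoglobulin and mitochondrial genes, and robust estimation off. Chosen after seeing the data were the erythroid list score as a covariate and a fit without Fpr2KO replicates 1 and 2. The edgeR step was tested on simulated data for this comparison over 15878 genes. It recovered 20% of 50 genes changed 1.5-fold, 70% of 50 changed 2-fold, 92% of 50 changed 3-fold and 94% of 50 changed 4-fold, with 10 false calls among 148. The changed genes were drawn from those of at least 1 CPM, and simulated genes varied independently, without the erythroid differences between these libraries. With 148 calls the Benjamini-Hochberg cut on the unadjusted p was also looser than with the 6 real calls. Recovery can thus be lower in the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.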

Results

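RNA sequencing counts were compared between spleens of WT mice (n = 3) and of mice lacking Fpr2 (Fpr2KO, n = 4). Fpr2 encodes a G protein-coupled receptor of myeloid cells that binds formylated peptides, annexin A1 and serum amyloid A. The WT libraries held 14968605, 16571130 and 16600334 counts. The Fpr2KO libraries held 17190397, 17637436, 16424799 and 18692809 counts. The series addresses the effect of Fpr2 deletion, and its labels imply a single comparison, Fpr2KO against WT.

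The targeted gene followed the labels in every library. Fpr2 (ENSMUSG00000052270, chromosome 17, 17887824 to 17893952, plus strand, GRCm38) had 537, 479 and 477 reads in the WT libraries and 0 in all 4 Fpr2KO libraries. This was 32.2 ± 3.40 CPM (SD, n = 3) in WT and at least 181-fold lower in Fpr2KO, taking 3 counts per library as the floor (exact permutation p = 0.0286, the smallest these samples allow; edgeR adjusted p = 2.27e-05). Fpr1, the neighbouring receptor for formylated peptides, had 41.0 ± 15.5 CPM in WT (n = 3) and 32.5 ± 3.11 in Fpr2KO (n = 4). Its log2 fold change of -0.33 (SE 0.22) did not pass edgeR's test (adjusted p = 1.0), and it was 0.02 without WT replicate 1. Fpr3 had 7 reads in all Fpr2KO libraries together and 0 in WT, too few to compare, and Fpr-rs3, Fpr-rs4, Fpr-rs6 and Fpr-rs7 had 0 reads in all 7 libraries. Only 2 of the 7 members of the formyl peptide receptor list were tested, so the list itself was not.

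Apart from Fpr2, spleens lacking the receptor differed from WT in 5 genes, all of them lower. Rhox5, an X-linked homeobox gene known from reproductive tissue, had 5.30 ± 0.225 CPM in WT (n = 3) and no read in any Fpr2KO library, which is at least 29.8-fold lower by the same floor. Amd2, a close copy of the S-adenosylmethionine decarboxylase gene Amd1, fell from 5.03 ± 0.304 CPM in WT to 0.697 ± 0.0794 in Fpr2KO (n = 4). Pira2, a paired immunoglobulin-like receptor of myeloid and B cells, fell from 34.5 ± 5.28 to 16.3 ± 1.39 CPM. Gm47283 and Gm21887, which fall outside the naming rule and were chosen after their values were seen, had 11.7 ± 1.5 and 4.34 ± 0.911 CPM in WT against 1 and 2 reads in all Fpr2KO libraries together.

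In edgeR's quasi-likelihood test 6 of 16089 genes passed, 6 lower and 0 higher, and all 6 differed at least 2-fold. Amd2 (chromosome 10, 35708675 to 35711892) had a log2 fold change of -2.84 (SE 0.22, edgeR adjusted p = 0.000762). Pira2 (chromosome 7, 3836812 to 3845051) had one of -1.08 (SE 0.13, edgeR adjusted p = 0.0201). Rhox5 (chromosome X, 37804842 to 37808876) and Gm21887 (chromosome X, 170009659 to 170019281) both had an edgeR adjusted p of 0.00105, and Gm47283 (chromosome Y, 90784738 to 90816464) one of 2.08e-05. The WT level was 837 times that of Fpr2KO for Gm47283 (95% counting interval 150 to 33070) and 155 times for Gm21887 (43.0 to 1283). Gm47283 lies on chromosome Y, and the sex of the mice was not given in the sources used here. Neither edgeR nor DESeq2 called the sex-dependent genes Xist, Ddx3y, Eif2s3y, Kdm5d or Uty, which were named after the calls were seen. A difference in sex was not otherwise tested. Reads of Amd2, Pira2, Gm47283 and Gm21887 are uncertain, because each has close relatives. Reads shared with a relative could have been assigned to it or left uncounted. Gm47283 and Gm21887 may thus not be 2 separate changes. Pira2 lost its call in 6 of the 7 fits that left out 1 library, all but that without WT replicate 3, with edgeR adjusted p between 0.0611 and 0.140 and log2 fold changes between -1.01 and -1.13. It also lost it without both Fpr2KO replicates 1 and 2 (-0.98, edgeR adjusted p = 0.325) and with limma-voom (-1.02, adjusted p = 0.0541).

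**Figure D1:**
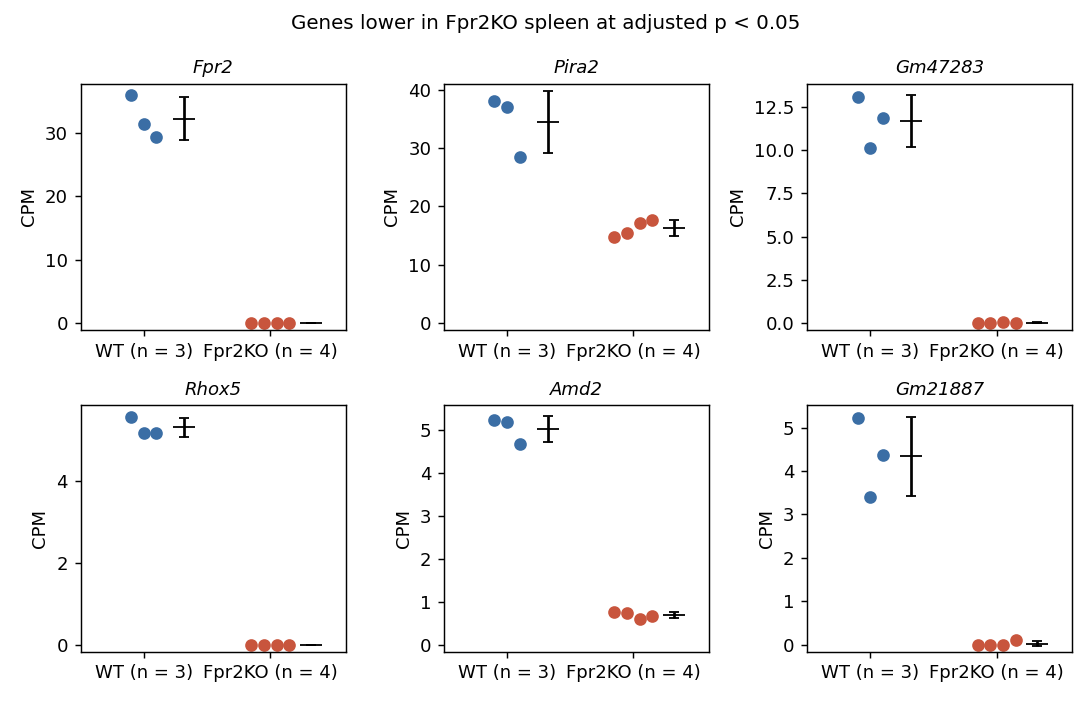
CPM of the 6 genes that passed the test, 1 point per library, with WT in blue (n = 3) and Fpr2KO in red (n = 4), on linear axes; bars give mean ± SD. All Fpr2KO libraries lie below all WT libraries, at 0 for Fpr2 and Rhox5 and at 16.3 ± 1.39 CPM for Pira2.

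In edgeR's test no gene passed as higher in Fpr2KO. The 5 with the smallest p, none of which passed that test, were Mgat3, a glycosyltransferase gene (log2 fold change 1.05, SE 0.17, edgeR adjusted p = 0.119), Adss (0.41), Skint3 (0.88), the growth factor receptor gene Fgfr4 (1.41) and the retinol esterification gene Lrat (0.80). The unadjusted p was under 0.05 for 802 genes, 308 higher and 494 lower, where chance gives 804. DESeq2 called 57 genes, 8 higher and 49 lower, and all 5 genes named here were among the 8. Without a low count filter edgeR called 21 genes, of which the 2 higher ones were Fgfr4 and Mgat3. The edgeR count was 10 without WT replicate 1 and 15 without WT replicate 3.

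None of the called genes lay near the targeted locus. Within 10 Mb of Fpr2, 0 of 225 tested genes besides Fpr2 passed, against 5 of 15819 elsewhere (two-sided Fisher exact p = 1). At an unadjusted p under 0.05 there were 12 genes in that window, or 5.33%, against 4.98% of all genes. DESeq2 called 1 gene there, Neurl1b (log2 fold change 0.83), which was chosen after its values were seen. Sytl3, on the same chromosome but outside that window, was also chosen after its values were seen. DESeq2 (log2 fold change -1.57) and edgeR without a low count filter (-1.58) called Sytl3, and the main comparison did not (edgeR adjusted p = 0.119). Nnt, which differs between C57BL/6N and C57BL/6J mice, had 1.6 ± 0.625 CPM in WT (n = 3) and 1.36 ± 0.193 in Fpr2KO (n = 4), a difference smaller than the spread between libraries.

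Neutrophil genes were lower as a group in Fpr2KO spleens. All 19 members of the list had a lower fitted level, with a median log2 fold change of -0.92, and the list passed camera with its preset correlation (adjusted p = 4.6e-12; adjusted p = 0.322 with an estimated correlation). The alarmin genes S100a9 and S100a8 had log2 fold changes of -1.06 (SE 0.21) and -1.03 (SE 0.23), the surface marker gene Ly6g one of -1.22 (SE 0.31) and the gelatinase gene Mmp9 one of -1.03 (SE 0.30). S100a9 had 1546 ± 174 CPM in WT (n = 3) and 743 ± 212 in Fpr2KO (n = 4). Over all genes 0 members passed edgeR's test, 9 had an unadjusted p under 0.05, and DESeq2 called 5. The groups did not overlap in 5 of the 19 members, and in 5.91% of all tested genes. S100a9, S100a8 and Ly6g passed when adjusted over the list alone. The list score did not separate the groups in an exact permutation test (p = 0.0857, or 0.463 adjusted over the lists), and Fpr2KO replicate 1 lay above WT replicate 1.

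**Figure D2:**
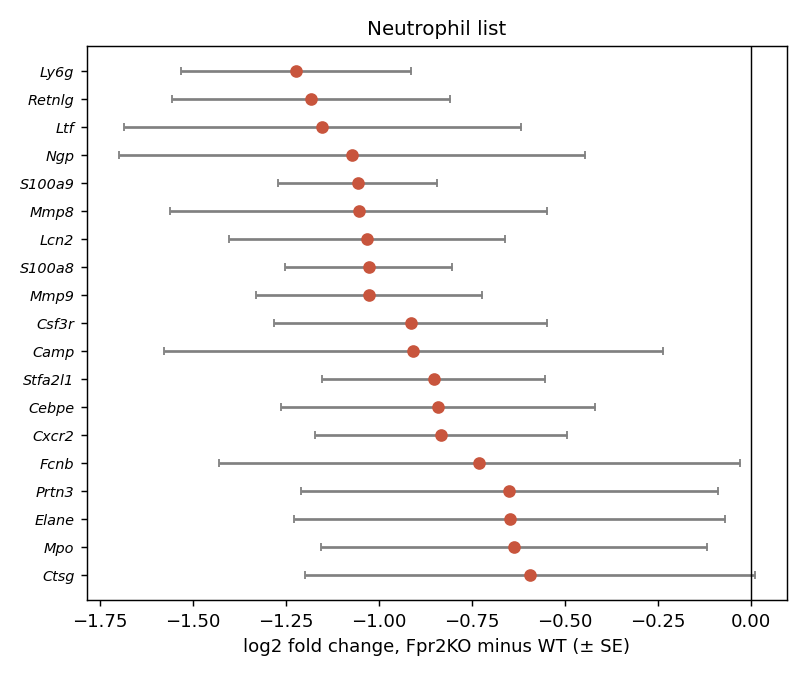
Fitted log2 fold change (Fpr2KO minus WT) of the 19 genes of the neutrophil list, with bars of ± SE on a log2 axis. All 19 points lie below 0, around a median of -0.92, with wider errors for the granule genes of immature cells.

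Transcripts of mast cells, basophils and eosinophils were also lower, with 11 of 13 genes lower and a median log2 fold change of -1.19 (camera adjusted p = 0.000207; adjusted p = 0.388 with an estimated correlation). Over all genes 0 passed edgeR's test, while 9 had an unadjusted p under 0.05 and DESeq2 called Hdc. Adjusted over the list alone, Cpa3 (-1.19), Fcer1a (-1.46), Mcpt8 (-1.68), Hdc and Prss34 passed as lower, and Ccr3 (0.42), an eosinophil chemokine receptor gene, as higher. Hdc and Prss34 fall outside the naming rule and were chosen after their values were seen. Cpa3 is a mast cell and basophil protease gene, Fcer1a a chain of the IgE receptor and Mcpt8 a basophil protease gene. The list score differed at an exact permutation p of 0.0286, or 0.257 adjusted over the lists. The groups were barely apart, with WT replicate 1 at -0.028 and Fpr2KO replicate 1 at -0.039. Mcpt8 and Prss34 overlapped between the groups.

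In the list of Fpr2 ligands and lipid mediator enzymes, which also holds receptor genes, 11 of 14 genes were lower. Its median was -0.25 (camera adjusted p = 0.00517, or 0.322 with an estimated correlation). No ligand gene passed edgeR's test, over all genes or over the list alone. The list shares Camp with the neutrophil list. Whether it and the phagocyte list below fell separately from the neutrophil genes was not tested. The lipoxygenase genes Alox5 (-1.30) and Alox15 (-1.49) passed when adjusted over the list alone, and over all genes with DESeq2 but not with edgeR. Alox5ap had a log2 fold change of -0.38 and Ltb4r1 one of -0.42, and neither passed with edgeR or DESeq2. Without WT replicate 3, Alox5 passed over all genes (edgeR adjusted p = 0.0162). The list of phagocyte NADPH oxidase and complement genes, 11 of 12 lower, had a median of -0.12 (camera adjusted p = 0.00517; adjusted p = 0.322 with an estimated correlation). Among its members with the smallest p were C5ar1 (-1.05), Ncf1 (-0.14) and C3ar1 (-0.52), none of which passed edgeR's test, while DESeq2 called C5ar1 (adjusted p = 0.0388). That list of phagocyte genes did not pass without WT replicate 3 (camera adjusted p = 0.119), without Fpr2KO replicate 1 (0.0629) or without both Fpr2KO replicates 1 and 2 (0.0990). The median was -0.06 without WT replicate 3, and that of the ligand list -0.41 without Fpr2KO replicate 1.

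NK and cytotoxic cell genes were slightly higher in Fpr2KO, 11 of 15, with a median log2 fold change of 0.11 (camera adjusted p = 0.000901; adjusted p = 0.322 with an estimated correlation). The activating receptor genes Ncr1 (0.50) and Klrk1 (0.32) and the receptor gene Klra8 (0.45) passed when adjusted over the list alone, and 0 did over all genes with edgeR or DESeq2. Klrd1 was at 0.28. The median was 0.27 without WT replicate 3 and 0.18 without Fpr2KO replicate 1. At an unadjusted p there were 4 members under 0.05. The list score was higher in each Fpr2KO library than in each WT library (exact permutation p = 0.0286, or 0.257 adjusted over the lists).

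**Figure D3:**
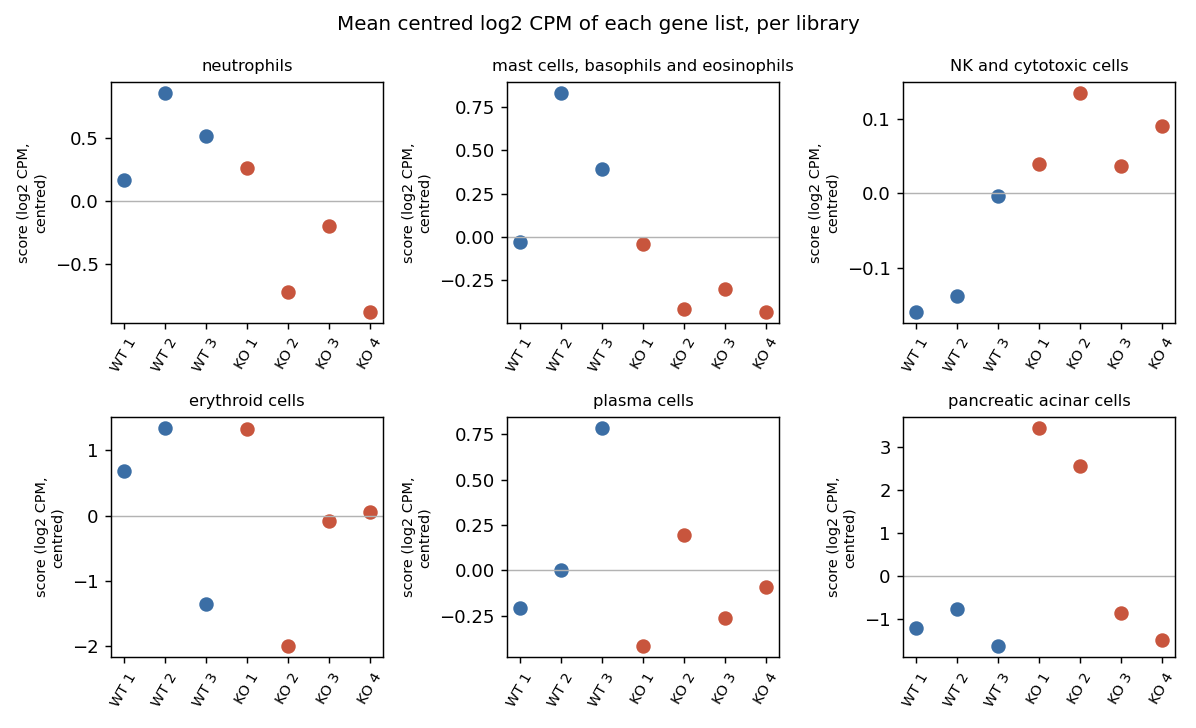
List scores (mean log2 CPM centred over the 7 libraries) for 6 gene lists, 1 point per library, WT in blue and Fpr2KO in red. The NK score is higher in all 4 Fpr2KO libraries, the erythroid score spans -2.0 to 1.34 with both groups mixed, and the pancreatic score is high only in Fpr2KO replicates 1 and 2.

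Pancreatic acinar transcripts stood out in 2 of the Fpr2KO libraries. The summed CPM of 20 acinar genes was 1092 in Fpr2KO replicate 1 and 606 in replicate 2, against 39.7 and 36.0 in replicates 3 and 4 and 32.5, 49.1 and 24.4 in WT. The 4 tested members Cela1 (1.21), Ctrl (4.43), Prss2 (6.06) and Zg16 (2.40) were higher in the fit, and the list passed camera (median 3.41, adjusted p = 0.00788; adjusted p = 0.671 with an estimated correlation). It did not pass without Fpr2KO replicate 1 (0.0822), without replicate 2 (0.0686) or without both (0.469). The median was 1.77, 2.17 and 0.10 in these fits, and from 8.24 to 8.83 with a WT library left out, when 18 members were tested. Over all genes 0 of the 4 passed edgeR's test and 0 had an unadjusted p under 0.05. Adipocyte genes, with 2 of 10 members tested and so no test, summed to 44.5 CPM in WT replicate 3 and to at most 4.67 in the other libraries.

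A further 4 lists passed camera as lower, each with calls that single libraries decided. Marginal zone macrophage genes had a median of -0.31 with 5 of 6 lower (adjusted p = 0.00788; adjusted p = 0.671 with an estimated correlation). Among them Siglec1 (-0.35), the scavenger receptor gene Marco (-0.42), Cd209b (-0.88) and Timd4 (-0.27) did not pass. The list did not pass without WT replicate 3 (0.130) or Fpr2KO replicate 4 (0.0628), and its median was -0.54 without both Fpr2KO replicates 1 and 2. Mitochondrially encoded genes were at -0.16 with 10 of 12 lower (adjusted p = 0.00517; adjusted p = 0.899 with an estimated correlation). Their smallest p belonged to mt-Atp6 (-0.40), mt-Cytb (-0.27), mt-Co1 (-0.21) and mt-Nd2 (-0.16), and the call was lost without WT replicate 2 (0.159), WT replicate 3 (0.119), Fpr2KO replicate 2 (0.0566) or both Fpr2KO replicates 1 and 2 (0.203). Without WT replicate 1 the mitochondrial median was -0.24.

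Megakaryocyte and platelet genes were lower in 14 of 14 cases (median -0.27, camera adjusted p = 0.0281; adjusted p = 0.918 with an estimated correlation). Treml1 (-0.41), Itgb3 (-0.31) and Vwf (-0.29) did not pass singly. The call was lost without WT replicate 2 (0.405), WT replicate 3 (0.733), Fpr2KO replicate 3 (0.121) or Fpr2KO replicate 4 (0.343). The median ranged from -0.51 without WT replicate 1 to -0.10 without WT replicate 3. Plasma cell genes were lower in 13 of 14 cases (median -0.33, camera adjusted p = 0.0281; adjusted p = 0.918 with an estimated correlation). The immunoglobulin constant region gene Ighg2c had a log2 fold change of -1.69 (SE 0.57) and Igha one of 0.93 (SE 0.47), while Prdm1 was at -0.32 and Fkbp11 at -0.67, and none passed. Single WT libraries weighed on both immunoglobulin genes. Ighg2c had 4487 CPM in WT replicate 3 against 1125 and 1685 in WT replicates 1 and 2. Igha had 1655 CPM in WT replicate 2 against 694 and 510 in WT replicates 1 and 3. The plasma cell list turned direction without WT replicate 3 (0.962) and did not pass without Fpr2KO replicate 1 (0.159), 3 (0.0505) or 4 (0.0567), or without both replicates 1 and 2 (0.0544). Its median was -0.50 without WT replicate 2 and -0.08 without WT replicate 3.

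The other 17 tested lists did not pass camera. Among myeloid lists, the median was 0.03 for monocytes (adjusted p = 0.899), with Ly6c2 (-0.52) lower when adjusted over the list alone and Itgam at -0.54. It was 0.05 for red pulp macrophages (0.291), with Cd163 at 0.49 and Slc11a1 at 0.18, and 0.13 for dendritic cells (0.107), with Clec9a at 0.30 and Clec10a at -0.46. Among lymphoid lists it was -0.05 for B cells (0.433; Cd37 -0.14, Cxcr5 -0.17), -0.09 for marginal zone B cells (0.439; Fcrl5 -0.35, Cd9 -0.12) and -0.23 for germinal centre B cells (0.229; Bcl6 -0.24, Fas -0.30). T cells had a median of 0.03 (0.725), with Il7r at -0.44 and Lef1 at 0.29, and regulatory and activated T cells one of -0.11 (0.222), with Tnfrsf4 at -0.41 and Tigit at -0.63. Stromal cells were at 0.00 (0.725; Col1a1 0.46, Col1a2 0.23) and endothelial cells at -0.04 (0.433; Pecam1 -0.13), where Lyve1 (-1.89), a marker gene of lymphatic and sinusoidal vessels, passed when adjusted over the list alone and, with DESeq2, over all genes (adjusted p = 0.0443).

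Erythroid genes had a median of -0.32 (camera adjusted p = 0.229), with Hba-a1 at -0.98 (SE 0.81) and Hbb-bs at -0.93 (SE 0.78). Single libraries decided this median. It was -1.07 without Fpr2KO replicate 1 and -0.82 without WT replicate 3, when the list passed as lower (0.000722 and 0.000117), and it turned to 0.24 without WT replicate 2 (0.506) and to 0.04 without Fpr2KO replicate 2 (0.342). Without Fpr2KO replicate 3 it was -0.19. Haemoglobin transcripts took between 1.01% and 7.95% of the counts of a library, with the lowest share in Fpr2KO replicate 2 and the highest in WT replicate 2. Among programme lists, the type I interferon response was at -0.03 (0.844; Oasl1 -0.26, Ifi44 0.31) and inflammatory cytokines at -0.08 (0.534; Socs3 -0.66, Il1rn -0.59). MHC class II presentation was at 0.03 (0.688; H2-DMb2 -0.10, H2-Aa 0.12) and immediate early and heat shock genes at -0.18 (0.0717; Zfp36 -0.23, Junb -0.23). Circadian and glucocorticoid genes were at 0.07 (0.597; Klf9 -0.49, Fkbp5 -1.04) and proliferation genes at -0.09 (0.274; Cdc20 -0.18, Mki67 -0.29). For monocytes and for the circadian list the mean (-0.02 and -0.08) and the median differed in sign. With an estimated correlation 0 of the 27 lists passed, the directional fry test passed 0 (lowest adjusted p 0.207), and its mixed form passed 2, NK and cytotoxic cells (0.00202) and mast cells, basophils and eosinophils (0.0246).

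The leading difference between the libraries went with the level of erythroid genes, which varied within both groups. The first principal component of log2 CPM took 36.4% of the variance and the second 18.0%. It followed the erythroid score across the 7 libraries (Pearson r = -0.994, exact permutation p = 0.000794, adjusted p = 0.00159; Spearman rho = -0.929, exact permutation p = 0.00675, adjusted p = 0.0135), of 2 relations computed. Without the 2 libraries farthest from the median score, r was -0.989. The erythroid genes are among those that make up the component, so the relation is partly built in. Only the erythroid and neutrophil scores were compared with it, so other lists may follow it too. The neutrophil score did not follow that component (r = -0.496, exact permutation p = 0.261, adjusted p = 0.261; rho = -0.5, exact permutation p = 0.267; r = -0.152 without the 2 farthest).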

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

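The tests that weigh explanations, the erythroid covariate, and the genes Cpb1, Cela2a and Amd1 were chosen after the results were seen. Of 117 values per Fpr2KO library examined for a single library far from the other 3 (by Dixon's gap over range, at its 95% critical value), 6 passed, where chance gives about 5.85. They were the CPM of Gm47283 and of Gm21887 (1.0 each, because only 1 library had any read), Mgat3 (0.873), Cpa3 (0.882), Marco (0.881) and Cd9 (0.837). Outside the main measurement, the 16 acinar genes too low to be tested summed to 784 CPM in Fpr2KO replicate 1 and 454 in replicate 2, against at most 1.05 in WT.

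Other splits of the 7 libraries into 3 and 4 were fitted in the same way. DESeq2 and edgeR without a low count filter were not run on these splits. Their larger counts therefore cannot be set against chance in this way. As many genes as the real 6 came from 2 of the 35 splits, the real one included, so chance cannot be excluded for the count of changed genes, nor for the 6 lower or the 6 changed at least 2-fold (2 of 35 each). The single other split that did so set WT replicates 1 and 2 with Fpr2KO replicate 1, the libraries with the highest erythroid scores, apart from the rest. It called 173 genes (166 lower, 45 at least 2-fold), which points to a structure of the samples. With the erythroid score as a covariate the real split called 14 genes, Fpr2 among them, and no other more than 4. That is 1 of 35, the smallest share possible, for a covariate picked after the planned count gave 2 of 35, so it does not settle the question of chance. These shares weigh the counts of genes and not single genes. Fpr2, the deleted gene, had 477 to 537 reads in the WT libraries and 0 in all Fpr2KO libraries, and Rhox5 had 79 to 84 and 0. For 10 passing lists 20 of 35 splits gave as many (highest other 15), so chance cannot be excluded there. For 0 genes higher and 0 near Fpr2 the count decides nothing, since all 35 splits give at least 0 (highest other 7 and 2).

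Neutrophil genes were lower in Fpr2KO by a median log2 fold change of -0.92. Differences in erythroid content are argued against as the whole cause, since the median stayed at -0.89 with the erythroid score as a covariate. Pancreatic tissue is argued against too, since the median was -1.16 without both libraries that held it. Chance cannot be excluded, because 3 of 35 splits gave a score difference as large (real size -0.90, highest other 1.05). If not chance, fewer neutrophils in these spleens may account for all 19 members being lower. Bulk counts do not part cell number from expression per cell, so both stay open. The fall was not uniform over the libraries, and the groups did not overlap in only 5 members. WT replicate 1 lay below the Fpr2KO mean for Camp (43.9 against 75.0 CPM) and Ngp (178 against 228). WT replicate 3 did so for Csf3r (127 against 132) and Stfa2l1 (4.31 against 4.47).

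Rhox5, Amd2, Gm47283 and Gm21887 were lower in all Fpr2KO libraries, the last 2 and Rhox5 at or near 0 reads and Amd2 at 10 to 14 reads per library. DNA flanking the Fpr2 locus is argued against, since 0 of the 4 genes lay within 10 Mb of it. Reads moved between Gm47283 and Gm21887 are argued against, since both together reached at most 0.104 CPM in Fpr2KO. That sum does not bear on reads given to other relatives or left uncounted, which was not tested. Reads of Amd2 moved to Amd1 cannot be told apart from a true loss: the gain of Amd1 exceeded the loss of Amd2 by 5.10 CPM, and its SE of 10.7 CPM is larger than the 4.33 CPM that Amd2 lost. A strain or substrain difference between the groups may account for all 4 and stays open, because the background of the Fpr2KO mice was not given in the sources used here. The log2 fold change of Nnt (-0.24, SE 0.31) bears at most on that locus.

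Pancreatic transcripts were high in Fpr2KO replicates 1 and 2. Pancreatic tissue taken with the spleen is a candidate explanation: 20 of 20 acinar genes lay above the highest WT library in both, among them Cela1 (150 and 76.7 CPM), Cpb1 (157 and 56.9) and Cela2a (106 and 74.9). Of these 20, Cela1 was also present in WT spleen, at up to 45.3 CPM. An effect of the genotype is argued against, since Fpr2KO replicates 3 and 4 reached at most 39.7 CPM in sum, within the WT range.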

How the results depend on the processing

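The erythroid covariate and the fit without Fpr2KO replicates 1 and 2 were chosen after seeing the data; the other alternatives were fixed beforehand. The count of 6 changed genes was also 6 with RLE and upper-quartile scaling, the stricter filter, the trimmed library size and robust estimation off, and 5 with limma-voom and without Fpr2KO replicates 1 and 2. DESeq2 called 57 genes (8 higher, 49 lower, 40 at least 2-fold) and 1 near Fpr2. Without a low count filter edgeR called 21 (2 higher, 19 lower, 15 at least 2-fold), and with the erythroid covariate 14, all lower. All 6 genes remained called in these 3 fits. Leaving out 1 library gave 5 to 15 changed and lower genes, and 5 to 10 changed at least 2-fold. The replicate numbers did not pair the samples (correlations of deviations 0.078, -0.434 and -0.073). With them as a replicate block 2 genes passed, both lower and at least 2-fold, namely Fpr2 and Gm47283, in a fit with fewer residual degrees of freedom. Scaling moved the median of all genes by under 0.02. Of 27 lists, 10 passed with the preset correlation, 0 with an estimated one, 0 by directional fry, 2 by mixed fry and 0 with the erythroid covariate and an estimated correlation. With that covariate and the preset correlation 13 passed, among them 3 that had not: germinal centre B cells (0.00141), regulatory and activated T cells (0.00211) and immediate early genes (0.0428). Proliferation passed without Fpr2KO replicates 1 and 2 (0.0099), and dendritic cells without WT replicate 1 (0.0445), WT replicate 3 (0.0327) or Fpr2KO replicate 1 (0.0141). Some other lists that had not passed also did so with 1 library left out, as their ranges show.

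Direction under the alternatives was followed only for the called genes and those that the naming rule took, not for all tested genes. None of these turned direction except with 1 library left out. The ranges were -0.49 to 0.0221 for Fpr1, -0.46 to 0.10 for Nnt and -0.74 to 0.0142 for Mki67. Lists that turned direction are given with their adjusted p; apart from plasma cells, none had passed. With the erythroid covariate these were T cells (0.504; 0.938 with an estimated correlation), erythroid cells (0.615; 0.763), proliferation (0.923; 0.981) and stromal cells (0.904; 0.965). MHC class II turned with the replicate block (0.932), with which the marginal zone macrophage (0.0786) and megakaryocyte (0.324) lists lost their calls, and B cells without Fpr2KO replicates 1 and 2 (0.681). Leaving out 1 library at a time turned several, with camera adjusted p from 0.506 to 0.947 for monocytes, 0.165 to 0.990 for B cells, 0.0234 to 0.884 for germinal centre B cells, 0.00293 to 0.962 for plasma cells and 0.0139 to 0.957 for T cells. The range was 0.0116 to 0.722 for regulatory and activated T cells, 0.000117 to 0.768 for erythroid cells, 0.187 to 0.947 for stromal cells, 0.130 to 0.654 for endothelial cells and 0.0505 to 0.803 for the interferon response. It was 0.0381 to 0.925 for inflammatory cytokines, 0.226 to 0.868 for MHC class II, 0.00335 to 0.922 for immediate early genes, 0.165 to 0.921 for circadian genes and 8.87e-07 to 0.552 for proliferation. Except where fewer samples explain them, the cause was not tested. At this depth and spread the simulated test found 20% of 1.5-fold changes, a share that can be lower in the real comparison. Smaller changes were thus mostly not detectable.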

Other observations

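The genes described here were chosen after their values were seen, except that the germline list and its bounds were written before that list was tested. Outside the fixed lists, Slpi, Padi4, Pglyrp1 and Chil1 were lower without passing edgeR's test in the main comparison. DESeq2 called all 4, and edgeR without a low count filter called Slpi, Padi4 and Pglyrp1. Slpi, a secreted protease inhibitor gene, was at 322 ± 42.3 CPM in WT (n = 3) and 184 ± 21.7 in Fpr2KO (n = 4), a log2 fold change of -0.81 (edgeR adjusted p = 0.0990). Padi4, which encodes a histone citrullinating enzyme, was at -1.17, the peptidoglycan recognition gene Pglyrp1 at -0.70 and Chil1 at -1.09. With the erythroid score as a covariate, 14 genes passed, all lower, among them S100a9, S100a8, Pglyrp1, Padi4, Slpi and Chil1 besides the 6 of the main comparison.

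Tdrkh, Lin28a, Rnf17 and Ly6k, best known from germ cells, were also lower without passing edgeR's test in the main comparison. DESeq2 and edgeR without a low count filter called all 4, and Tdrkh also passed with the erythroid covariate (edgeR adjusted p = 0.0302). Tdrkh was at 13.7 ± 2.38 CPM in WT (n = 3) and 6.00 ± 0.833 in Fpr2KO (n = 4), a log2 fold change of -1.19 (edgeR adjusted p = 0.0846). Lin28a was at -1.52 (0.102), Rnf17 at -1.50 (0.348) and Ly6k at -1.34 (0.260). Together with Rhox5 they raised the hypothesis that germline genes as a class are lower in Fpr2KO. A list of 47 other germline genes argued against it among genes that had not been called. Any gene called in the main comparison was left out, so that 0 of the list passed was fixed in advance. Of the 12 genes tested, 6 were lower and 6 higher. The median log2 fold change was 0.0557 (SD 0.51), and 0 had an unadjusted p under 0.05. The fall of the class would have needed a median below -0.50.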
